A study of Homo sapiens with 18 samples.

How the data were processed

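The series measured total RNA from primary normal human oral keratinocytes, the epithelial cells that line the mouth, after 24 h of exposure to ethanol and nicotine. Ethanol was at 0, 20 or 50 mM and nicotine at 0, 0.5 or 1 µM, and each of the 9 combinations was measured on 2 Affymetrix arrays, 18 in all. The labels number the replicates 1 and 2 and do not say whether they were separate cultures or donors. The p-values of genes and of permutation tests therefore measure only the spread between these samples.

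The deposited values are linear-scale intensities, 1 per probe set and array, made with MAS5 per the submitters' processing notes, which give no version and no settings. Each array's mean signal, after trimming 2% of probe sets at each end, came to 499.92, from which a scaling of every array to about the same mean is inferred. No background correction, normalization or replacement of low values was added before log2 was taken. The table held 54675 probe sets, 62 of them controls, and 11777 probe sets are not listed in the probe annotation used here. Of the 42898 listed, 41097 pair with 1 gene and 1801 with several; the latter were not used for any gene. Symbols were updated through the gene identifier for 41043 of the 41097. The 59 probe sets of XIST, TSIX and Y-linked genes were left out. No genome build is named by the sources used here, and no coordinates are given.

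For each of the 19740 genes, the probe set with the highest mean log2 signal over all arrays stood for the gene. Genes whose probe set lay below the median probe set, a signal of 57.8, were not tested, which left 12404 genes. A mean for each of the 9 combinations was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), and all p-values were two-sided and adjusted by the Benjamini-Hochberg method. A gene is said to have risen or fallen where its adjusted p was under 0.05. Each ethanol dose was compared with 0 mM as the mean over the 3 nicotine doses (6 arrays against 6), and nicotine likewise over the ethanol doses. Both non-zero doses of each agent were compared with each other. The 8 treated combinations were each compared with untreated cells (2 arrays against 2), all sharing the same 2 untreated arrays. A moderated F-test of the 4 interaction terms asked whether the agents' log2 changes added up. The number of arrays limits the precision of every value.

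Before the data were examined, 34 gene lists (898 entries, 800 of them on the array), the comparisons, the alternatives and the rule for naming genes were fixed. The 31 lists with 5 or more tested genes were tested with camera in limma at a preset correlation of 0.01, and again with a correlation estimated for each list. Camera compares the genes of a list with all other tested genes. At the preset correlation it treats genes as nearly independent, so its p-value is not a measure of the spread between samples. The median log2 change of a list is over its tested genes. The rule names, for each main comparison, up to 12 rises and 12 falls with the largest change among genes past the threshold with the same sign at all 3 doses of the other agent (for the combination, in all 4 pairs of arrays). With fewer than 5 such genes past the threshold it names the 5 smallest p in each direction, as values. It adds up to 4 members past the threshold of each list that passed, or else the 3 with the smallest p, the 6 genes with the smallest interaction p, and ADH7, ALDH2, ALDH1A3, ALDH3A1, CYP1A1, CYP1B1, CHRNA5 and HMOX1. Some of the genes so named are not described here. Genes named in the comparison of 50 with 20 mM ethanol were chosen after their values were seen.

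Alternatives fixed beforehand were quantile normalization, centring of each array on its median, no filter or a filter at the 75th percentile of probe sets (a signal of 417.2, 8015 genes), a pseudocount of 16, no variance trend, a term for replicate number, an additive model, a fit on only the arrays compared, every probe set on its own, an estimated list correlation, and leaving out each array in turn. Alternatives added after seeing the data were leaving out 1 array with a high actin ratio, alone and with quantile normalization, array weights, the log2 signal of the 18S ribosomal RNA control of each array as a covariate, and an exact permutation test of each list's array means within the doses of the other agent. Control probe signals were compared between ethanol doses by the same exact permutation test (216 permutations).

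The fit was tested on simulated data with 200 of the 12404 genes changed by known amounts. For 50 against 0 mM ethanol it found 40% of genes changed by 0.25 on the log2 scale, 78% at 0.5 and 94% at 1, with 7 false calls among 163. For 1 against 0 µM nicotine it found 28%, 64% and 94% at these sizes, with 7 false calls among 149. For 50 mM ethanol with 1 µM nicotine against untreated cells it found 0%, 34% and 70%, with 2 false calls among 101. The simulated errors were drawn independently for each gene and array, without an outlying array or correlation between genes. These rates may therefore not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were prepared with pandas 2.3.3 and numpy 2.4.6.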

Results

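Gene expression was measured in primary normal human oral keratinocytes exposed for 24 h to ethanol at 0, 20 or 50 mM together with nicotine at 0, 0.5 or 1 µM. The layout crossed both agents, with 2 arrays for each of the 9 combinations, so each dose of an agent was measured on 6 arrays. The questions were what each agent changed at each dose, and whether the agents changed genes together in another way than apart. The values are MAS5 signal intensities, and 12404 genes were bright enough to test. The median signal of an array lay between 55.0 and 91.4.

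The RNA control probes differed with the ethanol dose. The mean 18S ribosomal RNA control signal was 6353 ± 7260 at 0 mM, 2896 ± 352 at 20 mM and 1757 ± 537 at 50 mM (SD, n = 6). Over all 6 arrays each it was 2.68-fold lower at 50 than at 0 mM (exact permutation test, two-sided p = 0.00926, the smallest that the 216 permutations can give). The median signal of the arrays was 70.3 ± 10.5 at 0 mM, 62.8 ± 7.48 at 20 mM and 59.2 ± 4.13 at 50 mM, 1.18-fold lower at 50 than at 0 mM (exact permutation p = 0.0185). The actin 3'/5' signal ratio, a measure of RNA integrity, showed no such difference (exact permutation p = 0.398). One array, replicate 1 of 0 mM ethanol with 0.5 µM nicotine, stood apart, with an actin ratio of 6.23 against 1.37 to 1.95 on the other arrays and an 18S signal of 21080 against 925 to 4488. Without that array the 18S signal was 1.95-fold lower at 50 mM (exact permutation p = 0.00926).

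**Figure D1:**
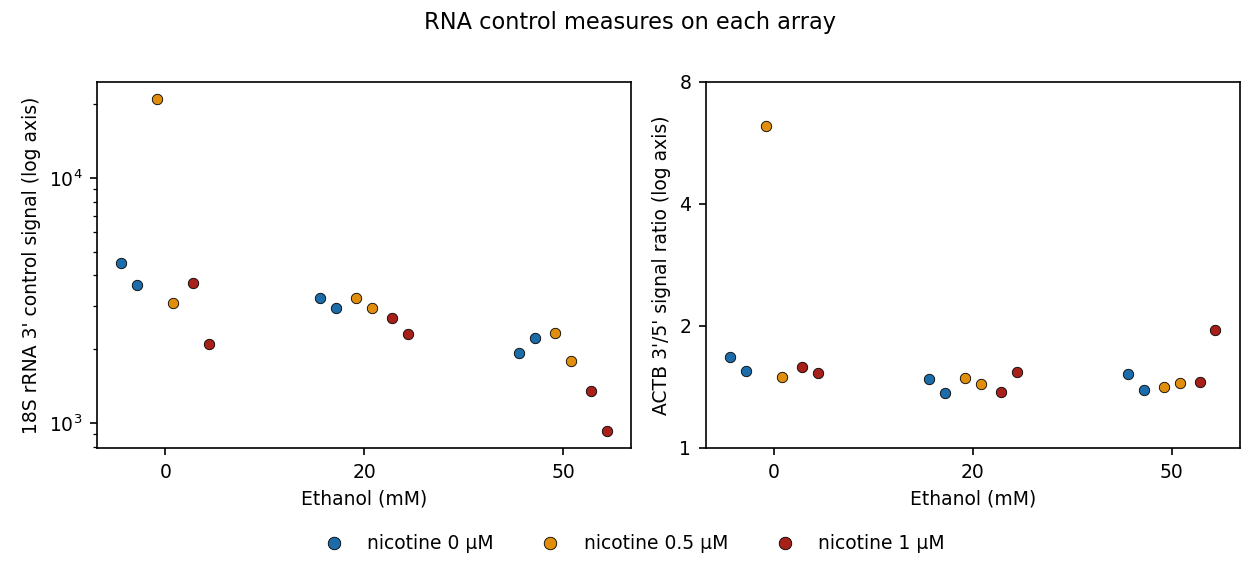
The 18S ribosomal RNA 3' control signal (left, log axis) and the actin (ACTB) 3'/5' signal ratio (right, log axis) of each of the 18 arrays by ethanol dose in mM, coloured by nicotine dose. The highest point in both panels is replicate 1 of 0 mM ethanol with 0.5 µM nicotine, at 21080 and 6.23.

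Ethanol at 50 mM changed 1123 genes against 0 mM, 586 higher and 537 lower, mostly by small amounts: the median size was 0.28 on the log2 scale, and 5 genes rose and 102 fell by 1.5-fold or more. The balance depends on the scaling of the arrays, with 977 higher and 453 lower after median centring and 307 and 324 after quantile normalization. It also depends on brightness, with 662 higher and 388 lower among the genes past the 75th percentile filter. The neutrophil-attracting chemokines CXCL2 and CXCL6 rose. CXCL6 rose by 0.68 ± 0.164 (log2 change ± SE, 6 arrays against 6; adjusted p = 0.0222) and CXCL2 by 0.66 ± 0.0706 (adjusted p = 0.000196). The zinc exporter SLC30A1 rose by 0.62 ± 0.17 (adjusted p = 0.036), and RIPK4, a kinase needed for epidermal differentiation, by 0.53 ± 0.0796 (adjusted p = 0.00287). TGFBI, a TGF-beta-induced matrix protein, rose by 0.48 ± 0.111 (adjusted p = 0.0202). The other large rises that the naming rule gave were XYLT1 (0.60), SINHCAF (0.55), PRRG4 (0.54), the cell cycle phosphatase CDC25A (0.54), UBL7-DT (0.52), KBTBD8 (0.51) and ZNF404 (0.50). Other probe sets of CDC25A, SINHCAF and PRRG4 had the opposite sign. TTC38 rose more than any of these (1.21, limma adjusted p = 0.00372) but gave -0.43 without nicotine, so the rule left it out. Its signals at 0 mM were 69.7, 46.5 and 52.3 at 0, 0.5 and 1 µM nicotine, so the size of its rise is uncertain. Over all 586 rises, 61.7% of the other probe sets had the same sign (median 0.07 against 0.22), and over the falls 79.7% (median -0.22 against -0.33).

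Of the falls at 50 mM, 12 are named here. ZBED6, a transcriptional repressor, fell by 1.43 ± 0.148 on the log2 scale (adjusted p = 0.000154), and the zinc finger gene ZNF800 fell by 1.14 ± 0.0923 (adjusted p = 2.81e-05), although its 2 other probe sets gave -0.33 and 0.12. The histone methyltransferase SETD1A fell (-1.68 ± 0.422, adjusted p = 0.0261), as did the calcium-responsive factor NFATC4 (-1.40 ± 0.372, adjusted p = 0.032) and the zinc finger factor IKZF1 (-1.32 ± 0.288, adjusted p = 0.016). The long noncoding RNA HOTTIP of the HOXA locus fell (-1.22 ± 0.247, adjusted p = 0.0122), and so did LOC101927166 (-1.79 ± 0.412, adjusted p = 0.0202). NOMO3 (-1.22), LOC401261 (-1.03), CCDC13 (-1.02), TMEM108 (-1.02) and CARD14 (-1.03), a scaffold of NF-kappaB signalling in keratinocytes, also fell. These are averages over the nicotine doses: without nicotine HOTTIP, LOC101927166, NOMO3 and CCDC13 gave -0.06, -0.01, -0.25 and -0.15 at 50 against 0 mM (2 arrays against 2). The mean signals of SETD1A, IKZF1, HOTTIP, NOMO3, CARD14, LOC401261 and TMEM108 at 50 mM (38.7, 52.2, 47.6, 48.4, 43.0, 52.7 and 39.0) lay under the 57.8 that a gene had to reach on average over all arrays, so the sizes of these falls are uncertain.

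**Figure D2:**
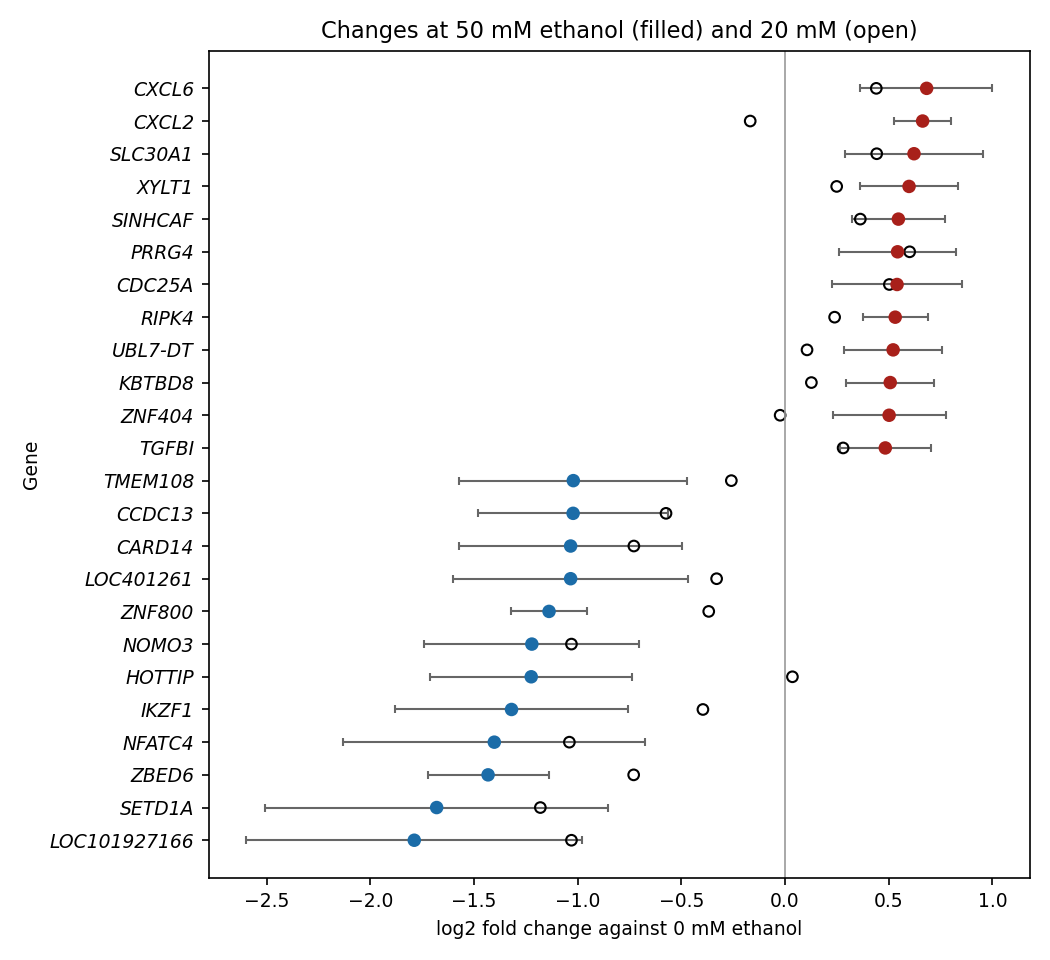
Log2 fold change against 0 mM ethanol of 12 rises and 12 falls, each named on the vertical axis. They are the largest at 50 mM among genes past the threshold with the same sign at every nicotine dose. TTC38 rose more but had the opposite sign without nicotine, so it is not shown. Filled points with bars are 50 mM with normal-approximation confidence intervals, and open points are 20 mM. The rises shown lie between 0.48 and 0.68 at 50 mM and the falls shown between -1.79 and -1.02, and CXCL2, ZNF404 and HOTTIP have the opposite sign at 20 mM.

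The 2 cell cycle lists stood higher at 50 mM by camera, with the smallest p-values among the lists (adjusted p = 3.08e-13 for G2 and mitosis and 4.46e-10 for S phase), but both had adjusted p = 0.412 with an estimated correlation. Of 37 tested genes of G2 and mitosis, all 37 had a higher mean and 12 rose (21 when adjusted over the list alone), with a median change of 0.21. Examples are KIF23, a kinesin of cell division (0.42 ± 0.0749), the cyclin-dependent kinase CDK1 (0.28 ± 0.0567), cyclin A2 (CCNA2, 0.46 ± 0.096) and securin (PTTG1, 0.17 ± 0.0371). Of 34 genes of S phase and DNA replication, 7 rose (18 when adjusted over the list alone), with a median of 0.20; among them were the helicase subunits MCM5 (0.30) and MCM6 (0.25), thymidylate synthase (TYMS, 0.19) and the ribonucleotide reductase subunit RRM2 (0.35). With the 18S signal as a covariate the S phase median was 0.05 (adjusted p = 0.0971). At least 1 other probe set of KIF23 (-0.06), MCM6 (-0.02) and, among the heat shock genes below, HSPH1 (-0.24) had the opposite sign. Of 17 cytosolic heat shock genes, 4 rose (5 when adjusted over the list alone): the chaperones and cochaperones DNAJA1 (0.28), HSPH1 (0.34), DNAJB1 (0.19) and FKBP4 (0.26). The heat shock list's median was 0.09 (adjusted p = 0.00104, and adjusted p = 0.0938 with an estimated correlation).

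The lists of early squamous differentiation, of the cornified envelope and late differentiation, and of wound keratins and alarmins stood lower at 50 mM by camera (adjusted p = 0.000196, 3.29e-05 and 0.000205 in that order), but had adjusted p = 0.3, 0.362 and 0.444 with an estimated correlation. Of 21 genes of early squamous differentiation, 6 fell and none rose (9 fell when adjusted over the list alone), with a median of -0.37; they include sciellin (SCEL, -0.37 ± 0.0687), KRT78 (-0.43 ± 0.102) and the differentiation factors GRHL3 (-0.41 ± 0.103) and OVOL1 (-0.37 ± 0.0942). Of 26 genes of the cornified envelope and late differentiation, 5 fell and none rose (6 fell when adjusted over the list alone), with a median of -0.29; they include envoplakin (EVPL, -0.51), SPRR2B (-0.39), corneodesmosin (CDSN, -0.51) and the protease inhibitor SPINK7 (-0.40). Of 10 keratins and alarmins of wounded keratinocytes, 4 fell and none rose (6 fell when adjusted over the list alone), with a median of -0.30: the antiproteases SLPI (-0.33) and PI3 (-0.43) and the alarmins S100A7 (-0.72) and S100A12 (-0.60). Hypoxia and glycolysis genes moved both ways, with 3 of 31 higher, the collagen hydroxylase P4HA1 (0.36), enolase (ENO1, 0.14) and PDK1 (0.28), and 1 lower, the angiogenic factor VEGFA (-0.40). That list's median was 0.09 (adjusted p = 0.000654, and 0.0557 with an estimated correlation), with 9 higher and 1 lower when adjusted over the list alone; 2 of the 3 other probe sets of ENO1 had the opposite sign.

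**Figure D3:**
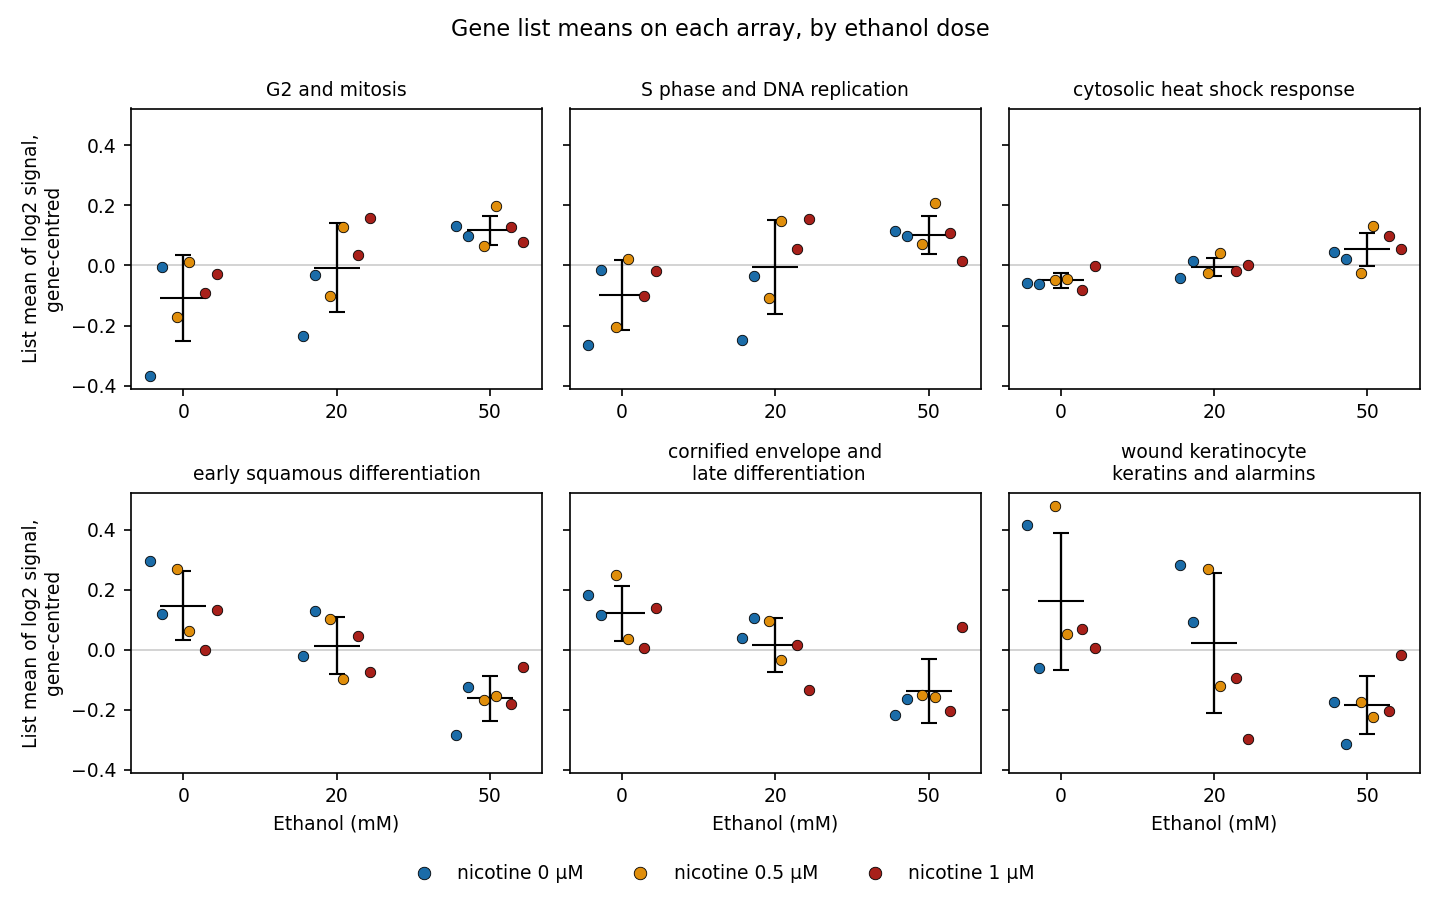
Mean over the genes of each list of the gene-centred log2 signal, 1 point per array, by ethanol dose in mM and coloured by nicotine dose; black bars and whiskers are the mean and SD of 6 arrays. The upper 3 lists had medians of 0.21, 0.20 and 0.09 at 50 against 0 mM, and the lower 3 of -0.37, -0.29 and -0.30.

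The 7 tested genes of alcohol and smoke metabolism and of nicotine response that were fixed beforehand did not pass at 50 mM. The aldehyde dehydrogenases ALDH2, ALDH1A3 and ALDH3A1 gave -0.06, 0.08 and -0.32 (adjusted p = 0.452, 0.549 and 0.117). The aryl hydrocarbon receptor targets CYP1A1 and CYP1B1 gave -0.31 and -0.22 (adjusted p = 0.303 and 0.423), the nicotinic receptor subunit CHRNA5 0.26 (adjusted p = 0.313) and haem oxygenase HMOX1 0.19 (adjusted p = 0.329). With the 18S signal as a covariate, ALDH2, ALDH3A1 and CYP1A1 had the opposite sign. ADH7, the stomach and oral alcohol dehydrogenase, was too dim to test (signal 48.5). The list of 14 ethanol and aldehyde oxidation genes had 1 gene lower, ALDH3A2 (-0.27, adjusted p = 0.0462), and none higher (list adjusted p = 0.53), and the 12 aryl hydrocarbon receptor targets had 1 higher, TIPARP (0.21, adjusted p = 0.0187), and none lower (list adjusted p = 0.397). The list of 12 acetylcholine receptor and cholinergic genes had a median of -0.25 and 1 member lower, LY6D (-0.61, adjusted p = 0.0333). LY6D counts here only as a member of the list fixed beforehand, and a cholinergic role of it was not tested. The list did not pass camera (adjusted p = 0.0539, and adjusted p = 0.3 with an estimated correlation). It passed the exact permutation test added later (adjusted p = 0.0287), but not without the array with the high actin ratio (adjusted p = 0.0718). The mean difference of the cholinergic list was -0.215 over all arrays and -0.190 without that array. Markers of fibroblasts (10 genes) and of salivary and simple epithelium (7 genes) had no gene past the threshold (adjusted p = 0.961 and 0.999), and the lists for leukocytes, endothelium and melanocytes had fewer than 5 tested genes.

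Of the 1123 genes, 1091 had the same sign at all 3 nicotine doses. They were chosen on the mean over these doses, so the choice itself favours this agreement. The 18S control signal and the median signal moved with the ethanol dose beside all of these gene groups. Without the array with the high actin ratio 763 genes passed (427 higher, 336 lower), and with the 18S signal of each array as a covariate 32 passed (13 higher, 19 lower). When each array was left out in turn, 312 to 2848 genes passed.

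Ethanol at 20 mM changed 5 genes against 0 mM, 1 higher and 4 lower. TMEM9B, a lysosomal membrane protein, rose by 0.42 ± 0.047 (6 arrays against 6; limma adjusted p = 0.0027). MDM4, an inhibitor of p53, fell (-0.44 ± 0.0683, adjusted p = 0.0455), as did the drug transporter ABCC10 (-0.32 ± 0.0475, adjusted p = 0.0385), the transcription factor CAMTA1 (-0.27 ± 0.0432) and the phosphatase PTPN13 (-0.26 ± 0.042; adjusted p = 0.0455 for both); 2 of the 4 other probe sets of MDM4 and 3 of the 4 of CAMTA1 had the opposite sign. At an unadjusted p under 0.05, 1999 genes passed, where chance alone would give about 620. The S phase and the G2 and mitosis lists stood higher (medians 0.11 and 0.12; adjusted p = 0.000154 and 8.62e-05) with no gene past the threshold, and both had adjusted p = 0.808 with an estimated correlation; CDK1 gave 0.18 and CCNA2 0.28 in values that did not pass. Replication-dependent histones stood lower (median -0.15, adjusted p = 0.0417, and 0.558 with an estimated correlation), with H2BC9 at -0.34, and hypoxia and glycolysis genes higher (median 0.08, adjusted p = 0.00835, and 0.127 with an estimated correlation), with ENO1 at 0.12 and VEGFA at -0.30. ALDH2, ALDH1A3, ALDH3A1, CYP1A1, CYP1B1, CHRNA5 and HMOX1 did not pass (adjusted p from 0.249 to 0.963). The count of 5 genes became 0 without a variance trend and in the additive model, and ranged from 1 to 1251 when each array was left out in turn.

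The changes at 20 mM mostly pointed the way they did at 50 mM. Of the 1123 genes that changed at 50 mM, 1082 had the same sign at 20 mM, with a median of 0.15 against 0.28; as both doses were compared with the same 0 mM arrays, part of this arises from the choice of genes. With the 0 mM arrays divided so that none was shared, the 1123 genes with the largest change at 50 mM relative to their spread had the same sign at 20 mM in 81.3% of cases (75.9% to 83.4% over 8 divisions), against 63.4% over all genes. Across genes, which are not independent replicates, the log2 changes at both doses correlated with r = 0.682 and covariance 0.0244. Both comparisons share the 0 mM arrays, and simulated doses without any effect gave r = 0.499 and covariance 0.00935. With the 0 mM arrays divided between the comparisons, r averaged 0.303 (0.222 to 0.384 over 20 divisions). The mean 18S control signal and the mean median signal also fell from 0 to 20 to 50 mM. Dividing the 0 mM arrays does not remove this, so an array-wide axis cannot be told apart from ethanol for this agreement.

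Between 50 and 20 mM ethanol, 20 genes differed, 7 higher and 13 lower at 50 mM. CXCL2 was higher by 0.83 ± 0.0706 (adjusted p = 6.78e-05), having shown -0.17 at 20 against 0 mM. The prostaglandin E2 receptor PTGER4 was higher by 0.39 ± 0.0489 (adjusted p = 0.00244) and TTC38 by 1.40 ± 0.187 (adjusted p = 0.00388). The value of TTC38 comes from the nicotine-treated cells, as without nicotine its signals were 51.9 at 50 mM and 53.2 at 20 mM, and its size is uncertain because all its signals at 20 mM (45.4 to 53.2) lay under 57.8. DDIT4, a stress-induced inhibitor of mTORC1, was lower (-0.41 ± 0.0385, adjusted p = 0.000155), as was ZNF800 (-0.77 ± 0.0923, adjusted p = 0.00209). Without the array with the high actin ratio, 74 genes differed.

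Nicotine at 1 µM changed no gene past the threshold against 0 µM, averaged over the ethanol doses (limma, 6 arrays against 6). At an unadjusted p under 0.05, 960 genes passed, where chance alone would give about 620. The smallest p belonged to the chromatin protein UBN1 (-0.41, adjusted p = 0.151), the tropomyosin TPM4 (-0.56, adjusted p = 0.151), the ubiquitin-conjugating enzyme UBE2H (-0.32, adjusted p = 0.175), ZNF800 (-0.50, adjusted p = 0.213) and TMEM9B (-0.25, adjusted p = 0.213) among lower values, and to the RNA helicase DDX46 (0.26, adjusted p = 0.28) and SFTA1P (0.28, adjusted p = 0.476) among higher ones. Type I interferon response genes stood higher as a list, with a median of 0.21 over 36 genes, 32 of them with a higher mean (adjusted p = 8.47e-12, and 0.534 with an estimated correlation). None of them passed over all genes and 13 did when adjusted over the list alone; ISG15, a ubiquitin-like protein induced by interferon, gave 0.33, the helicase DDX60 gave 0.36 and DTX3L gave 0.30.

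The other lists that passed for 1 µM nicotine had no gene past the threshold and lost their calls with an estimated correlation (adjusted p from 0.367 to 0.536). Higher were G2 and mitosis (median 0.13, adjusted p = 3.26e-08; MKI67 0.28), S phase (0.09, adjusted p = 0.000655; POLA1 0.24) and replication-dependent histones (0.10, adjusted p = 0.0447; H2BC9 0.32). Lower were ribosomal proteins (-0.12, adjusted p = 4.67e-10), wound keratins and alarmins (-0.16, adjusted p = 0.00765), basal keratinocyte genes (-0.09, adjusted p = 0.00989; KRT5 -0.16), hypoxia and glycolysis (-0.03, adjusted p = 0.0257) and the NRF2 antioxidant response (-0.04, adjusted p = 0.0281; FTL -0.13). The median of the ribosomal proteins was 0.006 after quantile normalization. The same 7 metabolism and receptor genes, from ALDH2 to HMOX1, did not pass (adjusted p from 0.743 to 0.957), with CHRNA5 at 0.05 and CYP1A1 at -0.16.

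Nicotine at 0.5 µM also changed no gene past the threshold (limma; 535 genes at an unadjusted p under 0.05, where chance alone would give about 620). The smallest p belonged to the lipase maturation factor LMF1 (-0.99 ± 0.184, adjusted p = 0.914) and to TSPAN32 (1.47 ± 0.316, adjusted p = 0.982). The S phase list (median 0.09, adjusted p = 7.65e-05; PCNA 0.14) and the G2 and mitosis list (median 0.08, adjusted p = 3.07e-07; AURKB 0.21) stood higher, each with adjusted p = 0.94 with an estimated correlation. CHRNA5 gave 0.31 (adjusted p = 0.982). Between 1 and 0.5 µM no gene passed either (606 at an unadjusted p under 0.05).

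The combination of 50 mM ethanol with 1 µM nicotine changed 44 genes against untreated cells, 8 higher and 36 lower (2 arrays against 2). CXCL2 again rose, by 0.72 ± 0.122 (adjusted p = 0.0179), and with it CAD, the enzyme that starts pyrimidine synthesis (0.52 ± 0.0829, adjusted p = 0.0107), and SAE1, a subunit of the SUMO-activating enzyme (0.51 ± 0.0821, adjusted p = 0.0113). ZNF219 (0.51), SACM1L (0.49), PPTC7 (0.40), the splicing factor SF1 (0.39) and COPRS (0.36) also rose. HOTTIP fell (-2.91 ± 0.428, adjusted p = 0.00598), from a signal of 116 to 15.4, far under 57.8 and near the lower quartile of these arrays (14.1 and 15.1), so the size of its fall is uncertain. It gave -0.06 with 50 mM ethanol alone and -0.17 with 1 µM nicotine alone and did not pass the interaction test (adjusted p = 0.721). The falls included ZBED6 (-2.00 ± 0.256, adjusted p = 0.00155) and ZNF800 (-1.88 ± 0.16, adjusted p = 6.84e-05). TPM4 (-1.34 ± 0.161, adjusted p = 0.000974) and UBN1 (-1.18 ± 0.117, adjusted p = 0.000271) also fell. The kinase CDC42BPA (-1.41), the chromatin proteins GATAD1 (-1.13) and NSD3 (-0.93), ANKRD17 (-1.06), LMO7 (-0.95), RABL3 (-0.93) and the interferon regulatory factor IRF5 (-0.92) fell too.

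Of these 44 genes, 40 had also changed at 50 mM ethanol averaged over nicotine, all 40 in the same direction, but the arrays of the combination are among those of that comparison. On arrays the combination does not use (50 mM with 0 and 0.5 µM against 0 mM with 0.5 and 1 µM), 39 of the 44 had the same sign, with a median size of 0.19 against 0.70. Other probe sets of the 36 falling genes changed less, with a median of -0.10 against -0.72 for the tested ones, and 71.0% of them had the same sign. Among the genes named, at least 1 other probe set of SF1, PPTC7, ZNF800, CDC42BPA, ANKRD17, LMO7, NSD3 and RABL3 had the opposite sign. The lists that passed were those of 50 mM ethanol without hypoxia: G2 and mitosis (median 0.29, adjusted p = 8.26e-12; KIF23 0.57), S phase (0.22, adjusted p = 5.84e-06; POLA1 0.46), heat shock (0.12, adjusted p = 0.0104), early squamous differentiation (-0.36, adjusted p = 0.000712; KRT78 -0.72), cornified envelope (-0.25, adjusted p = 0.00225) and wound keratins and alarmins (-0.29, adjusted p = 0.00906). With an estimated correlation the adjusted p of these lists lay between 0.447 and 0.735. None of their genes passed over all genes, and adjusted over the list alone 16 of G2 and mitosis, 4 of early squamous differentiation and 1 of heat shock did. None of the 7 metabolism and receptor genes passed, with CHRNA5 at 0.39 (adjusted p = 0.562) and ALDH3A1 at -0.36 (adjusted p = 0.477). Without the array with the high actin ratio, which is in neither group but enters the shared spread, 133 genes passed (54 higher, 79 lower); without replicate 1 of the untreated cells 10 passed, and without replicate 2 of the combination 12.

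The other 7 combinations changed no gene past the threshold against untreated cells (limma, 494 to 1490 genes at an unadjusted p under 0.05, where chance alone would give about 620). For 50 mM ethanol alone this number was 1182 and for 1 µM nicotine alone 494.

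No gene passed the test of an ethanol by nicotine interaction (limma moderated F-test; 758 genes at an unadjusted p under 0.05, where chance alone would give about 620). The smallest p belonged to SLFN5, an interferon-induced gene, whose combined change at 50 mM and 1 µM differed from the sum of the separate ones by -0.70 on the log2 scale (adjusted p = 0.152). TMEM9B followed (adjusted p = 0.286), then SNRNP200, ESF1, TTC38 and ANKRD36B (adjusted p = 0.336 each). TTC38 had signals of 203 and 198 at 50 mM ethanol with 0.5 and 1 µM nicotine and of 45.4 to 69.7 in the other 7 combinations, while its probe set is near the lower limit of the test.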

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

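Replicate 1 of 0 mM ethanol with 0.5 µM nicotine stood apart on probes that the comparisons do not use: its actin 3'/5' ratio was 6.23, where the highest untreated array had 1.68, and its 18S control signal was 21080, where the highest untreated array had 4488. The 18S covariate was added after seeing the data, and the tests of this array and of quantile normalization, the division of the list test on 18S into S phase and the other lists, and the exact test of the 18S signal were chosen after the results were seen.

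The first pattern weighed is the set of 1123 genes that changed at 50 mM ethanol. Of 100 splits of the same arrays within nicotine doses, only 1, the real one, gave as many genes, and the highest other gave 19. This argues against chance for these samples, provided that single arrays can be exchanged. The labels do not say whether replicates were separate cultures, and the share was not adjusted over the comparisons, so chance is not excluded. Without the array with the high actin ratio the genes kept 88.4% of their median change, and after quantile normalization 94.2%. Taken apart, the rises and the falls kept 85.2% and 85.9% after quantile normalization. These values argue against either as the whole cause. With the 18S signal of each array as a covariate they kept 65.6%, while the median standard error grew from 0.0656 to 0.0896. Then 32 genes passed, 20 of them among the 1123, so the loss of calls came from both a smaller change and a larger error. Each combination had its own mean, so the covariate was fitted on differences between replicates. The widest lay between the array with the high actin ratio and its replicate (18S signals of 21080 and 3099). No fit with the covariate was made without that array, so the covariate's results may rest largely on that 1 array. An effect of ethanol and an array-wide axis that follows the 18S signal cannot be told apart here, because the 18S signal itself was lower at 50 mM even without that array (exact permutation p = 0.00926); an effect of ethanol may act on both.

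The second pattern weighed is the higher cell cycle lists and lower squamous lists at 50 mM ethanol. As many lists as the 7 seen passed in 31 of 100 splits. The other splits gave a median of 4 lists and 12 in the highest, so chance cannot be excluded for the number of lists. That count covers lists of any kind and does not test these lists in particular. The exact permutation test added later gave adjusted p = 0.0287 for G2 and mitosis, S phase and early squamous differentiation. For the cornified list it gave adjusted p = 0.0521. Without the array with the high actin ratio it gave adjusted p = 0.0718 for each of these lists. With the 18S covariate the median of the S phase list kept 24.7% of its size (0.20 to 0.05, camera adjusted p = 0.0971). An axis that follows 18S may account for most of it, but the covariate may rest largely on the array with the high actin ratio. Without that array the S phase median was 0.16. Of the G2 and mitosis, early squamous and cornified lists the least kept was 48.6%. All 3 still passed camera at the preset correlation (adjusted p = 0.00691, 0.00227 and 0.00691), but lists also passed that test in other splits, so this gives little support. For these 3 lists the axis and ethanol cannot be told apart. After quantile normalization the least kept by any of the 4 lists was 65.8%, between the bounds set for the scaling of the arrays, which stays open as a part of the change.

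The third pattern weighed is that other probe sets of the genes that fell at 50 mM moved less than the tested ones (-0.22 against -0.33 in 293 genes); those of the genes that rose also moved less (0.07 against 0.22) and were not tested further. Other probe sets within 1 log2 unit of the tested one in brightness moved 50.9% as much (-0.18 against -0.35 in 159 genes). A gap due to a compression of dim probe sets should be smaller among these than over all other probe sets, and it was not. No spread was measured for either gap, and the value lies between the bounds set for it, so compression stays open only as a part of the gap. Choosing probe sets for their change on the arrays with 0 and 0.5 µM nicotine, and measuring them on the arrays with 1 µM, gave a ratio of 1.18 (-0.26 against -0.22 in 101 genes), so selection of the tested probe set is a candidate explanation for part of the gap. That test used the 200 falling genes with the smallest p, because 13 genes (7 lower) passed on those arrays. No biological explanation was tested for this pattern.

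For the other comparisons, 1 of 100 splits, the real one, gave the 20 genes that differed between 50 and 20 mM (highest other 5). This argues against chance for that count but does not exclude it. The share is the smallest that 100 splits can give and was not adjusted over the comparisons. At least the 5 genes of 20 mM ethanol came from 4 of 100 splits, the real one included, with 89 genes in the highest. That share lies under the bound set beforehand but was not adjusted over the comparisons. The count of 5 also depended strongly on the processing, so chance cannot be excluded for it. The split with 89 genes gave 1 gene without the array with the high actin ratio, so that array may account for it. For nicotine at 1 µM, at 0.5 µM and between them no gene passed, so all 100 splits give as many whatever the data and nothing follows from them. Their highest counts were 2, 114 and 1 genes; the split with 114 points to a structure of the samples that was not identified, and it gave 224 without that array. For the lists, 60 of 100 splits gave the 4 of 20 mM ethanol or more (highest 13), 18 the 9 of 1 µM nicotine (highest 12) and 86 the 2 of 0.5 µM nicotine (highest 11), so chance cannot be excluded for them.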

How the results depend on the processing

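On the probe set tested, no named gene past the threshold changed sign in any refit. Of the 77 results past it that the naming rule gave, 44 had other probe sets, and in 18 at least 1 of these had the opposite sign. The medians of 2 lists changed sign: ribosomal proteins at 1 µM nicotine, 0.0059 after quantile normalization (adjusted p = 0.829), and wound keratins and alarmins in the combination, 0.0542 with the 18S covariate (adjusted p = 0.852). With the 18S covariate, 3 genes that did not pass at 50 mM ethanol changed sign: ALDH2 to 0.0536, ALDH3A1 to 0.0795 and CYP1A1 to 0.0473, also without passing. Of 100 named results past the threshold, all kept it with a pseudocount of 16, 75 after quantile normalization, 66 without a variance trend, 78 without the high actin array and 20 with the 18S covariate; 39 kept it whichever array was left out. The 1123 genes at 50 mM ethanol, where still tested, kept their signs in every refit of the genes except that with the 18S covariate, where 1112 did and 11 changed sign. The array-out, weight, 18S and exact permutation settings were chosen after seeing the data. Fewer arrays, fewer or more genes tested and a larger error act by construction; other causes were not tested. Genes under a signal of 57.8 were not tested, so nothing is said of them.

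The count of 1123 genes at 50 mM became 631 after quantile normalization, 746 without a filter, 648 without a trend, 706 on only the arrays compared, 1869 with every probe set, 386 without the array and with quantile normalization, and 32 with 18S. Of the 631 and the 32, 540 and 20 were among the 1123. Median centring gave 977 higher and 453 lower (68.3% higher, against 52.2%). The 5 genes at 20 mM became 1 with centring (higher, 100%, against 20%), 2 without a filter, 22 with the 75th percentile filter, 0 without a trend, 0 in the additive model, 1 on only the arrays compared, 2 with every probe set, 1 with weights and 11 without the array and with quantile normalization. The 0 genes of 1 µM nicotine became 1 with every probe set. The 20 genes between 50 and 20 mM became 36 on only the arrays compared, 176 with every probe set, 74 without the array, 96 with weights, 46 without the array and with quantile normalization, and 37 with 18S; centring gave 45.8% higher, against 35%.

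The 44 genes of the combination became 28 without a trend, 15 on only the arrays compared, 547 with every probe set, 133 without the array, 105 with weights and 127 without the array and with quantile normalization. Where none passed, 50 mM ethanol alone gave 1 under each of quantile normalization, the array out, weights, and the array out with quantile normalization; 50 mM with 0.5 µM gave 1 with quantile normalization, no filter, the 75th percentile filter or the array out, 5 with every probe set, 6 with weights and 5 without the array and with quantile normalization. With 18S, 1 µM nicotine alone gave 1. With every probe set, 4 genes had an interaction.

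No list passed with an estimated correlation (0 in all 5 comparisons). The 7 lists of 50 mM became 11 without the array. The 4 of 20 mM became 2 with quantile normalization, 9 with centring, 7 without a filter, 8 without the array and 0 by exact permutation. The 9 of 1 µM nicotine became 4 with quantile normalization, 14 with the 75th percentile filter, 3 without the array and with quantile normalization, 5 with 18S and 0 by exact permutation. The 2 of 0.5 µM became 4 without the array, 4 with 18S and 0 by exact permutation. Exact permutation passed 10 lists at 50 mM (adjusted p = 0.0287, the smallest possible p being 0.00926), among them fatty acid synthesis, cholinergic genes, replication-dependent histones and DNA and histone modifying enzymes, which had not passed camera, but not the cornified list (adjusted p = 0.0521), and without the array the smallest adjusted p was 0.0718. Without the array the mean differences of the 10 lists all kept their sign and were somewhat smaller. For G2 and mitosis the change was from 0.225 to 0.195, and for wound keratins and alarmins from -0.345 to -0.274.

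The labels do not say what the replicate numbers mean. Differences between replicates correlated from -0.189 to 0.175 over 36 pairs of groups (8 over 0.1), so the numbers were not taken to pair the samples. The replicate block gave 1424 genes at 50 mM, 14 at 20 mM, 1 at 1 µM nicotine, 41 between 50 and 20 mM, 8 at 50 mM with 0.5 µM and 102 in the combination.

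With each array left out in turn, a lone array was assumed to vary like the other groups. Genes ranged from 312 to 2848 at 50 mM, 1 to 1251 at 20 mM, 0 to 2 at 1 µM and 0 to 50 at 0.5 µM nicotine, 11 to 74 between 50 and 20 mM, 0 to 209 between 1 and 0.5 µM, 0 to 1652 for 0.5 µM nicotine alone, 0 to 1 for 1 µM alone, 0 to 2 for 20 mM alone, 0 to 9 for 20 mM with 0.5 µM, 0 to 4 for 20 mM with 1 µM, 0 to 3 for 50 mM alone, 0 to 36 for 50 mM with 0.5 µM, 10 to 135 for the combination and 0 to 491 for the interaction. Lists ranged from 7 to 11, 3 to 8, 7 to 14, 0 to 4 and 1 to 8, for 50 mM, 20 mM, 1 µM, 0.5 µM and the combination. The values 2848, 1251, 50, 209, 1652, 135 and 491 arose without replicate 2 of 0 mM with 0.5 µM, which leaves the high actin array alone in its group and there lets all 6 named interaction genes pass, and 74 without the high actin array. The count at 20 mM moved by over 1.5 times without 16 of the 18 arrays. At 50 mM, 327 genes passed without untreated replicate 1, 475 and 427 without replicates 1 and 2 of 0 mM with 1 µM, 481 and 479 without those of 50 mM alone, 312 without replicate 2 of 50 mM with 0.5 µM, and 484 and 479 without those of the combination. For the combination, 10 genes and 1 list passed without untreated replicate 1, and 12 genes without its replicate 2.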

Other observations

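The genes, families and tests of this part were chosen after their values were seen, except that the lists and the test of the zinc finger family with the 18S covariate were set down first; the members of that family were later limited to protein-coding genes. At 50 mM ethanol, cytokine genes moved both ways: beside the rises of CXCL2 and CXCL6, TSLP, an epithelial cytokine of allergic inflammation, fell (-0.62 ± 0.132, adjusted p = 0.0147), as did the granulocyte growth factor CSF3 (-0.51 ± 0.129, adjusted p = 0.0278), the chemokine CCL20 (-0.30, adjusted p = 0.0438) and TNFAIP3, an inhibitor of NF-kappaB signalling (-0.25, adjusted p = 0.014). Over the 32 tested cytokines and chemokines, 2 rose and 4 fell, and the list did not pass (adjusted p = 0.277). Among 25 immediate early and EGFR ligand genes 4 rose and 1 fell, with IER2 at 0.37 and the AP-1 member FOSL1 at 0.38 among the rises and MYC at -0.20 the fall (list adjusted p = 0.265). Of 30 genes of the unfolded protein response and amino acid stress 1 rose and 4 fell, among them DDIT4 (-0.39), TRIB3 (-0.25) and asparagine synthetase (ASNS, -0.21); the list's adjusted p was 0.964.

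Of 37 genes of proteasome subunits and regulators (PSMA to PSMF), 11 rose at 50 mM ethanol and none fell, including PSMD1 (0.36), PSMC3 (0.33) and PSME3 (0.39). The mean over the family was higher by 0.12, and all 6 arrays at 50 mM lay beyond those at 0 mM (exact permutation p = 0.00926, adjusted over 8 families 0.0148). Camera gave p = 0.00125 with an estimated correlation. The mean difference was 0.07 after quantile normalization and 0.11 with the 18S covariate, and at 20 mM it was 0.09. The family was chosen for the rises of its members on the same arrays, so this test gives no separate support for an effect of ethanol. Of 8 chaperonin subunits 3 rose (mean 0.10, exact permutation p = 0.00926).

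Zinc finger genes and long noncoding RNAs had lower means at 50 mM. Of 360 protein-coding genes named ZNF, 45 fell and 6 rose, with ZNF43 at -0.80 and ZNF302 at -0.42, and the family mean was -0.15 (exact permutation p = 0.00926, adjusted 0.0148; camera p = 0.0171 with an estimated correlation). With the 18S covariate 54.6% of this mean was kept (-0.08), which lies between the bounds set for it. An array-wide axis that follows the 18S signal therefore cannot be told apart from ethanol for this family. After quantile normalization the mean was -0.05, so the scaling of the arrays may account for much of it. Of 608 long noncoding RNAs 36 fell and 1 rose, with a mean of -0.19 (exact permutation p = 0.00926, but camera p = 0.14 with an estimated correlation). Their median was -0.19 before and -0.04 after quantile normalization, so the scaling of the arrays may account for most of it. Without the array with the high actin ratio the mean was -0.12.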
